A study of Mus musculus with 72 samples.

How the data were processed

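Gene expression in bone marrow of C57BL/6 mice, a common inbred laboratory strain fed without restriction, was measured on 72 array samples from 36 mice. Total RNA of each mouse was labelled with a radioactive nucleotide, per the labels' protocols, and hybridised to 2 cDNA arrays, called array A and array B here, with 8448 clones each. The deposited values are scores: each array's values have a mean of 0 and an SD of 1 over its clones, as was checked in every column. The scanner, the background treatment and any log step before this scaling are not given in the sources used here. A difference of 1 unit is therefore 1 SD of the clones of an array, and no fold change can be given. The authors' scores carry no unit of brightness, and the level of a gene is relative to the other clones of the same array. No column of per-sample values was left unmapped (0 columns).

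Clones were named through the platform annotation supplied with the tables. Of the 16896 clones, 9663 had 1 gene, 212 on array A and 224 on array B had several, and 3448 and 3349 were unnamed here. The gene identifiers of 9641 of the named clones were found in the RefSeq table, and 0 symbols needed an update. A gene was the mean of its clones on an array, and a gene on both arrays was taken from the array with more of its clones (array A where these were equal), which gave 7151 genes. Clones of the same gene resembled each other little. The intraclass correlation of their mean levels was 0.0778 on array A (713 genes with 2 or more clones) and 0.182 on array B (561 genes). For the 963 genes with clones on both arrays, the levels correlated at r = 0.0463 and the age slopes at r = 0.0046 across genes, which are not independent replicates. Gene names are therefore those of the annotation, and the value under a name is that of its clones. It was not tested clone by clone whether each name stands on the right clone, and some may not. The Y-linked genes Eif2s3y (mean -0.589 in females, -0.619 in males) and Uty (-1.39 and -1.38) had like levels in both sexes. If the sexes are as labelled, the values under these names did not follow the named genes. The 21 clones named as haemoglobin genes all had a mean above 1 in the mice fitted, the lowest being 1.47.

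The design, the main tests, the gene names written into the 26 lists and the rule for named genes were fixed before the data were examined. That design used all 36 mice. The reported fits use 34, a departure chosen after the data were seen. The columns of mice 66 (male, 704 to 743 days) and 67 (female, 704 to 743 days) did not follow the clone order of their own tables. Their correlation with the mean of the other mice was 0.128 to 0.138 on array A and -0.012 to -0.0112 on array B, against at least 0.839 and 0.962 for each of the other 34 mice. With the mean of the other table it was 0.694 to 0.719 and 0.781 to 0.79. The choice was made on this identity of rows, and counts from all 36 mice as deposited are given beside the reported ones. It left 4 males and 1 female in the oldest group. The description of mouse 27 repeats that of mouse 1, and the title and characteristics were used for it.

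Linear models were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with sex and either age in days or age class as terms, all mice sharing an estimate of the spread. Slopes are per year. P-values were adjusted over the 7151 genes by the Benjamini-Hochberg method, with a threshold of 0.05. No mouse was hybridised again to the same array. The spread therefore holds that of arrays and handling together with that between the mice, which are separate animals. Their number limits the precision: the median SE of a gene was 0.041 for the slope, 0.0718 for the step from 17 to 44 days to 169 to 194 days, and 0.0871 for 704 to 743 days against 169 to 194 days. The 26 gene lists covered blood and marrow cell types, bone, cartilage, fat, muscle and vessel cells, and cell processes. A listed name was matched to a measured symbol, or to an older name only where it was not itself the symbol of another gene. This matching was corrected after results had been seen, which took 3 wrongly matched genes out of the lists. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry beside it, adjusted over the 26 lists. List tests for 476 to 499 days and for the slope by sex were added after the design was fixed.

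By the rule for named genes, the 12 strongest genes per direction past the threshold and with the same direction in males and females would be named (for sex, in at least 3 of the 4 age ranges), and where fewer than 5 qualify, the 5 with the lowest p in each direction are given as values. The second case applied throughout. Up to 4 members of a list with the largest moderated t serve as examples. Which lists are described gene by gene was settled after the data were seen: the 3 with the lowest camera p per comparison, those with a gene passing when adjusted over the list alone, and the X and Y chromosome lists.

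The fits were tested on simulated data made from permuted residuals of the 34 mice, with 200 of 7151 genes changed. For the step to 169 to 194 days, 30.1% of changes of 0.2, 83.7% of 0.4 and 98.8% of 0.8 were recovered. For 704 to 743 days these were 13.7%, 69.6% and 96.7%, for sex 49.5%, 92.4% and 99.8%, and for the slope 76.9%, 98.7% and 99.8%. The changes were added to the gene values, so these rates are for shifts in those values. They do not tell how far a change in a named transcript moves the values of its clones. With no change simulated, camera at the preset correlation called at least 1 list in 61 of 100 data sets for the slope, 45 for the step to 169 to 194 days, 51 for 704 to 743 days and 51 for sex. With an estimated correlation these were 1, 0, 2 and 0, and with fry 13, 8, 9 and 5. A list call at the preset correlation alone therefore has little weight here. For 704 to 743 days, a shift of 0.1 in the erythroid list was called in 87 of 100 data sets at the preset correlation and in 24 with an estimated correlation.

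Alternatives fixed in advance were quantile normalization, a filter on dim genes (taken over the mice fitted), single clones, rounds of the running number in the titles as a block, the running number as a covariate, array weights, trend and robust eBayes, a fit per table, the log of age, mice of 169 days and older, linear age in the sex comparison, and leaving out mouse 27 or each mouse in turn. Alternatives added after seeing the data were all 36 mice as deposited, the 2 mice with their tables exchanged back, leaving out mice 1 and 2, 3 sizes of correction for position on the array, 5 surrogate variables (limma), array weights and the running number as a covariate for lists, and, for sex and the slope by sex, a block for each pair of a male and a female of 1 age range with neighbouring running numbers. The position correction assumed blocks of 24 rows and 22 columns, inferred from the correlation of deviations along the table. Surrogate variables from the sva package were also tried while the data were explored and called 0 genes in each of the 6 comparisons.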

Results

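Bone marrow of 36 mice, 19 males and 17 females, was compared by age and by sex. The ages fell into 4 ranges, 17 to 44 days (9 mice), 169 to 194 days (10), 476 to 499 days (10) and 704 to 743 days (7). In the fits, 34 mice were used, 18 males and 16 females, with 5 mice in the oldest range. Values are z-scores within an array, so differences are in SD units of the clones. No gene passed in any of the 6 comparisons, and genes named below are given with their values, not as changes.

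**Figure D1:**
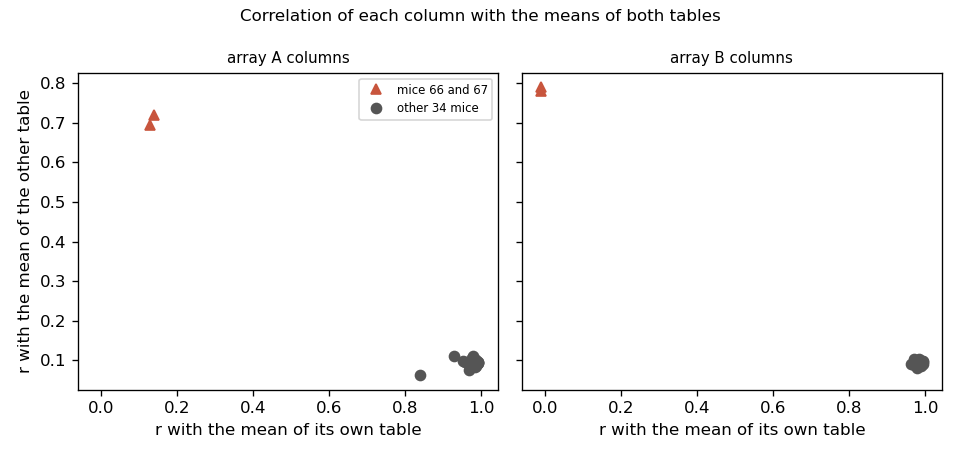
Correlation of each mouse's column with the mean of the other mice on its own table (x axis) and on the other table (y axis), for array A and array B, with 1 point per mouse. The 34 mice used lie at 0.839 or above on the x axis, and mice 66 and 67 lie at 0.138 or below on it and at 0.694 or above on the y axis.

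The first comparison asked whether expression followed age in days. Among genes of monocytes, macrophages and antigen presentation, 13 of 19 had a positive slope and 6 a negative one, with a mean of 0.0265 per year. Its examples were H2-Eb1, a class II histocompatibility gene (0.104 ± 0.0391 SE), Ctsl, a lysosomal protease (0.116 ± 0.0465), Irf8, a transcription factor of monocyte development (0.111 ± 0.048), and Cd74, the invariant chain (0.0702 ± 0.032). Of 12 neutrophil genes 8 had a positive slope, with Lcn2 at 0.163 ± 0.0811, S100a9 at 0.122 ± 0.0634, Cybb at 0.0459 ± 0.0341 and Csf3r at 0.0494 ± 0.0435. Of 63 cell cycle genes 41 had a negative slope, among them Ccna2, which encodes cyclin A2 (-0.16 ± 0.0504), Kif11 (-0.0989 ± 0.0493) and Fen1 (-0.0633 ± 0.0353), while Chek1 had a positive slope of 0.136 ± 0.0505. Ighm, the immunoglobulin mu heavy chain, had a slope of 0.195 ± 0.0643 and was the 1 gene in the lists that passed when adjusted over the list alone (adjusted p = 0.0317 over 7 B-lineage genes, limma). With each of 26 lists adjusted on its own at 0.05, chance gives about 1 list with a pass in a comparison. Across alternatives this p was 0.000724 to 0.287 and the slope 0.131 (all 36 mice as deposited) to 0.342 (smallest position correction), and the pass was lost in 7 of 17. Among the 7 were all 36 mice as deposited (adjusted p = 0.124), which does not test the pass, and the 2 mice exchanged back (0.0821). The pass was also lost without males of 704 to 743 days, replicates 1 (adjusted p = 0.0873) and 2 (0.0982, the fit without mouse 27 already counted among the 7), the female of that age (0.121), males of 17 to 44 days, replicate 2 (0.071), females of that age, replicate 4 (0.0539), or females of 476 to 499 days, replicate 3 (0.0526). Over all genes its adjusted p was 0.963, and the other B-lineage examples Sox4 (-0.0301 ± 0.0354), Cecr2 (-0.0319 ± 0.0424) and Tcf3 (-0.0162 ± 0.0323) lay within 1 SE of 0.

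The positive slopes with the lowest p were those of Gm8709 (0.136 ± 0.0366), Ccdc130 (0.0988 ± 0.0274), Fbxl20 (0.12 ± 0.0357), Eed, a Polycomb component (0.17 ± 0.0513), and E2f5 (0.154 ± 0.0478). The negative ones were those of C1galt1 (-0.276 ± 0.0831), Alad, an enzyme of heme synthesis (-0.256 ± 0.0787), Ccna2, Chchd2 (-0.141 ± 0.0465) and D5Ertd579e (-0.107 ± 0.0357). With limma, 0 of 7151 genes passed, the lowest adjusted p was 0.963, and 277 had an unadjusted p below 0.05, where 0.05 of all genes is 357.6. When age was exchanged between mice within sex, the median count over the other splits was 262, so 277 was not low for these data. With all 36 mice as deposited, 0 passed and 2556 had an unadjusted p below 0.05. Both mice added there belong to the oldest range and their columns follow the other table, so 2556 cannot be read as a count of age effects. With these 2 mice exchanged back 0 passed and 955 had an unadjusted p below 0.05, but after exchange they still stood apart from the rest. None of the 26 lists was called by camera (lowest adjusted p = 0.276), with an estimated correlation, or by fry, and 2 lists had an unadjusted camera p below 0.05.

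From 17 to 44 days to 169 to 194 days, which spans growth to young adulthood, 15 of 19 genes of monocytes, macrophages and antigen presentation were higher and 4 lower, with a mean of 0.0544. The mean of the list was -0.396 ± 0.0504 (SD, n = 9) in the younger mice and -0.34 ± 0.0395 (n = 10) in the older ones. Its examples were Irf8 (0.182 ± 0.0785 SE), the Fc receptor genes Fcgr3 (0.141 ± 0.0704) and Fcer1g (0.189 ± 0.0966), and Cd74 (0.0952 ± 0.0567). Camera called this list at the preset correlation (adjusted p = 0.0421), and the call was lost with an estimated correlation (adjusted p = 0.148) and with fry (adjusted p = 0.25). In simulated data without any change, camera at the preset correlation called at least 1 list in 45 of 100 data sets. It was also lost without dim genes (mean 0.0299, adjusted p = 0.253), with array weights (0.0389, 0.162), without mice 1 and 2 (0.0355, 0.239), with all 36 mice as deposited (0.0548, 0.0624) or exchanged back (0.0546, 0.0693), and with the middle position correction (0.0442, 0.0502). Leaving out any of 8 mice singly lost it too: females of 17 to 44 days, replicates 1 (adjusted p = 0.115) and 3 (0.112), males of that age, replicates 3 (0.0906) and 4 (0.0897), males of 169 to 194 days, replicates 1 (0.198) and 4 (0.183), and females of that age, replicates 1 (0.083) and 5 (0.0502).

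In the same comparison 48 of 67 ribosomal protein genes were higher, with a mean of 0.0275, among them Rpl7a (0.142 ± 0.0557), Rps28 (0.118 ± 0.0584), Rps20 (0.119 ± 0.0944) and Rpl5 (0.138 ± 0.111), and this list was not called (adjusted p = 0.149). The neutrophil list, with 8 of 12 genes higher, was not called either, with Lyz2 at 0.21 ± 0.119, S100a9 at 0.18 ± 0.113, Ceacam1 at 0.06 ± 0.0513 and Alox5ap at -0.0966 ± 0.085. Col2a1, the type II collagen of cartilage, was lower by 0.144 (-0.144 ± 0.0536), and passed when adjusted over the list alone (adjusted p = 0.0332 over 3 cartilage genes, limma) but not over all genes (adjusted p = 0.999). This too was 1 list of 26, as many as chance gives. Across alternatives the p over the list alone was 0.00374 to 0.973, and the pass of Col2a1 was lost with the 3 position corrections (-0.1, -0.0719 and -0.0915) and with the 2 mice exchanged back (-0.151 ± 0.236). It was also lost without 9 single mice: males of 17 to 44 days, replicates 1 (adjusted p = 0.0536), 3 (0.0874) and 4 (0.0514), females of that age, replicates 2 (0.0502), 3 (0.0734) and 5 (0.0663), males of 169 to 194 days, replicate 3 (0.0683), and females of that age, replicates 1 (0.0542) and 4 (0.105). The other cartilage genes, Col9a3 (-0.0149 ± 0.0652) and Hapln1 (-0.0019 ± 0.0576), were near 0. The higher genes with the lowest p were Psap, which encodes prosaposin (0.278 ± 0.0686), Tbc1d8 (0.294 ± 0.0746), Alkbh1 (0.235 ± 0.0714), Fgfbp1 (0.254 ± 0.0792) and Naaa (0.288 ± 0.0902). The lower ones were Ablim1 (-0.629 ± 0.191), Nudt16l1 (-0.713 ± 0.221), Myo10 (-0.245 ± 0.0761), Mttp (-0.414 ± 0.129) and U2surp (-0.132 ± 0.0412). With limma 0 of 7151 genes passed, the lowest adjusted p was 0.999, and 264 had an unadjusted p below 0.05; these counts were 0 and 66 with all 36 mice as deposited.

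Between 169 to 194 days and 476 to 499 days, young adulthood and middle age, the 3 cartilage genes were all higher at the later age, with a mean of 0.056. Of 7 endothelial genes 6 were higher (mean 0.0403), and of 68 genes of oxidative phosphorylation, the respiratory chain of mitochondria, 45 were higher and 23 lower (mean 0.0186). Of 14 interferon response genes 9 were lower and 5 higher (mean -0.0146). None of the 26 lists was called by camera (lowest adjusted p = 0.841), with an estimated correlation or by fry, and 0 had an unadjusted camera p below 0.05. With limma 0 of 7151 genes passed, the lowest adjusted p was 0.995, and 234 had an unadjusted p below 0.05. Among all 36 mice as deposited these counts were 0 and 50.

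In mice of 704 to 743 days, against 169 to 194 days, 19 of 22 erythroid and heme genes were lower and 3 higher, with a mean of -0.085. The list mean was 0.378 ± 0.0535 (SD, n = 10) at 169 to 194 days and 0.291 ± 0.0715 (n = 5) in the oldest mice. At 17 to 44 days the mean was 0.368 ± 0.0429 (n = 9) and at 476 to 499 days 0.4 ± 0.101 (n = 10), so the list did not fall steadily with age. For the age slope this list was not called (camera, adjusted p = 0.719). Examples were the heme synthesis genes Alad (-0.446 ± 0.17 SE) and Urod (-0.205 ± 0.0946), and the alpha-globin genes Hba-a2 (-0.162 ± 0.0745) and Hba-a1 (-0.161 ± 0.0774). All 21 haemoglobin clones had lower values in the oldest mice, with a median of -0.165, and such clones can hybridise to each other's transcripts, so they are not independent. Camera called the list at the preset correlation (adjusted p = 0.0012), and the call was lost with an estimated correlation (adjusted p = 0.919) and with fry (adjusted p = 0.96). An exact 2-sided permutation test of the list mean, exchanging age class within sex in 756 ways, gave p = 0.0529. It used a fit of its own to the 5 and 10 mice of these 2 age ranges alone, in which the difference was -0.0813. In all 36 mice as deposited the mean was -0.0829 and the list was not called (adjusted p = 0.332).

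Ribosomal protein genes were lower in 52 of 67 cases, with a mean of -0.046. Rps3a1 (-0.16 ± 0.0873), Rps12 (-0.143 ± 0.087) and Rplp1 (-0.146 ± 0.0934) were among them, and Rpl7l1 was higher (0.0982 ± 0.0626). The list was called at the preset correlation (adjusted p = 0.00578) and not with an estimated correlation (adjusted p = 0.98) or fry (adjusted p = 0.96). Without replicate 1 of the oldest males the mean was -0.0059 (adjusted p = 0.962), and without replicates 1 and 4 of the males of 169 to 194 days in turn it was -0.0282 (adjusted p = 0.176) and -0.033 (0.0841). The call was also lost with the middle position correction (-0.0306, camera adjusted p = 0.0558). With all 36 mice as deposited the mean was -0.146 and the list was not called (adjusted p = 0.0719). For the reason given above, that fit does not test the call. With the 2 mice exchanged back the ribosomal list was called at the preset correlation. In simulated data without any change, 51 of 100 data sets had at least 1 list called at the preset correlation. Of 26 antioxidant genes 18 were lower, among them Gpx3 (-0.166 ± 0.0818), Nfe2l2 (-0.1 ± 0.056), Mgst1 (-0.103 ± 0.0754) and Prdx3 (-0.125 ± 0.0995), and the list was not called (adjusted p = 0.443).

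**Figure D2:**
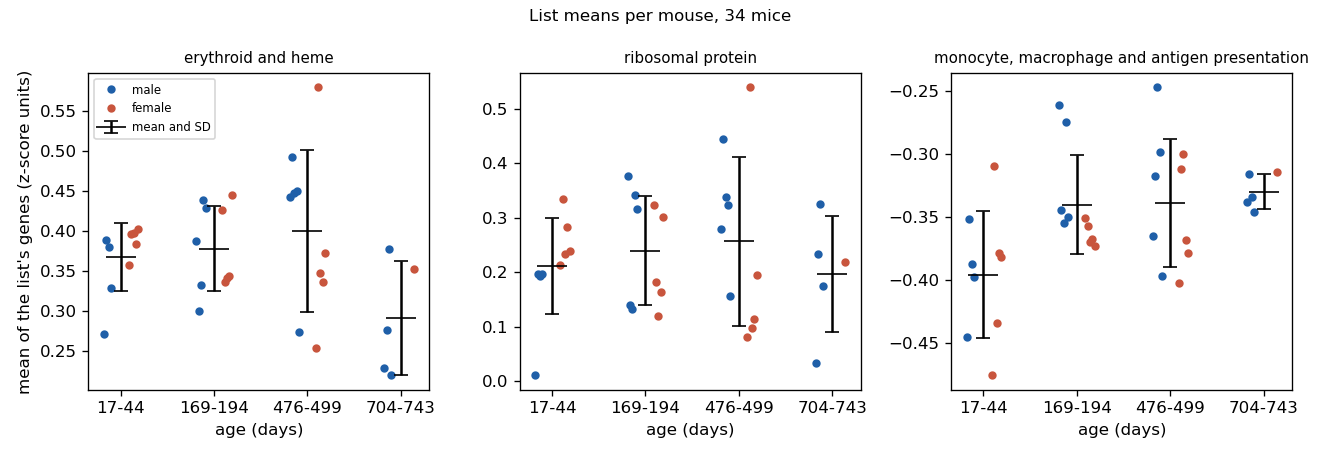
Mean of the genes of 3 lists in each of the 34 mice (y axis, z-score units) by age range in days (x axis), with 1 point per male or female mouse and the mean and SD of each age range as black bars. The erythroid mean was 0.378 at 169 to 194 days and 0.291 at 704 to 743 days, with SDs of 0.0535 and 0.0715.

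The higher genes with the lowest p in the oldest mice were Vps26c (0.298 ± 0.0921), Tubb2a-ps2 (0.219 ± 0.0714), Pias2 (0.277 ± 0.0927), Mbnl3 (0.248 ± 0.0867) and Zfp981 (0.241 ± 0.0849). The lower ones were Zfp36l2 (-0.229 ± 0.0755), Xkr8 (-0.185 ± 0.0647), Eri3 (-1.14 ± 0.397), Pcnx (-0.269 ± 0.0974) and Nisch (-0.139 ± 0.0525). Eri3 was at -1.42 in males fitted alone and at 0.058 in females, of which only 1 was in the oldest range, and it was at 0.174 with the 2 mice exchanged back. With limma 0 of 7151 genes passed, the lowest adjusted p was 1, and 136 had an unadjusted p below 0.05. With all 36 mice as deposited 0 passed, the lowest adjusted p was 0.0529, and 3420 had an unadjusted p below 0.05. Both mice whose columns followed the other table belong to the oldest range, so 3420 cannot be read as a count of age effects. With these 2 mice exchanged back 0 passed and 1015 had an unadjusted p below 0.05, but they still stood apart from the rest.

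Between the sexes, Xist, the RNA of the inactive X chromosome, had the lowest p of all genes. Its level was -1.14 ± 0.237 (SD, n = 16) in females and -1.38 ± 0.152 (n = 18) in males, a difference of -0.245 ± 0.0687 SE for males minus females. The sexes overlapped: 14 of 16 females lay above the male median, the lowest female was at -1.77 and the highest male at -1.14. Xist passed when adjusted over the list alone (adjusted p = 0.00661 over 6 genes of X inactivation and escape, limma) and not over all genes (adjusted p = 1), again 1 list of 26. Unlike the passes of Ighm and Col2a1, that of Xist was lost in 0 of the 16 alternatives that kept the gene (adjusted p over the list alone 0.00216 to 0.0415, limma). The filter on dim genes took Xist out, so its pass was not tested there. With each of 34 mice left out in turn the pass was lost 0 times (6.81e-05 to 0.015). In 15 pairs of a male and a female with neighbouring running numbers, Xist was higher in the female in 13, lower in 1 and equal in 1. Kdm6a (0.0719 ± 0.0781), Pbdc1 (-0.067 ± 0.0811) and Ddx3x (-0.033 ± 0.05), from the same list, did not differ by more than 1 SE. The Y-linked genes Eif2s3y (-0.0273 ± 0.083) and Uty (0.0083 ± 0.0639) differed between the sexes by less than 1 SE, so their clones gave no check of the labelled sex.

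Of 12 neutrophil genes 10 were higher in males, with a mean of 0.052, among them Anxa1 (0.195 ± 0.0935), S100a9 (0.167 ± 0.0863), Lyz2 (0.0772 ± 0.0914) and Lcn2 (0.0821 ± 0.112). Of 8 adipocyte genes 6 were higher in males, among them Fasn, which encodes fatty acid synthase (0.162 ± 0.0908), Dgat1 (0.0897 ± 0.0766), Acly (0.0818 ± 0.0702) and Lpl (0.0363 ± 0.0395). Of 19 monocyte genes 12 were higher, with Axl at 0.134 ± 0.0561, Lgmn at 0.104 ± 0.0768, Fcgr3 at 0.0695 ± 0.054 and Fcer1g at -0.0814 ± 0.0742. No list was called (lowest adjusted p = 0.131 for the neutrophil list). The other genes with the lowest p were Exd2 (0.156 ± 0.0495), Rbm22 (0.202 ± 0.0673), Actn4 (0.116 ± 0.0457), Psap (0.133 ± 0.0526) and Thnsl1 (0.124 ± 0.0497), higher in males, and Plrg1 (-0.13 ± 0.0455), Ppp1r2 (-0.133 ± 0.0474), Rpa2 (-0.109 ± 0.0408) and Rsad2 (-0.279 ± 0.105), lower in males. With limma 0 of 7151 genes passed, the lowest adjusted p was 1, and 88 had an unadjusted p below 0.05. These counts were 0 and 20 with all 36 mice as deposited.

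The last comparison asked whether the slope with age differed between males and females. Of 67 ribosomal protein genes 56 had a higher slope in males than in females and 11 a lower one, with a mean difference of 0.047 per year. Camera called this list at the preset correlation (adjusted p = 0.00617), and the call was lost with an estimated correlation (adjusted p = 0.871) and with fry (adjusted p = 0.804). It was also lost without any of 6 single mice: males of 17 to 44 days, replicate 1 (mean 0.0239, adjusted p = 0.308), females of that age, replicate 2 (0.0351, 0.16), males of 476 to 499 days, replicate 2 (0.039, 0.0778), and females of that age, replicates 1 (0.0305, 0.602), 3 (0.0339, 0.293) and 4 (0.0356, 0.242). Without both mice 1 and 2 the mean was 0.0284 (adjusted p = 0.469), and with array weights 0.0399 (0.0565). The other 25 lists were not called (lowest adjusted p = 0.659). The 5 genes with the lowest p were Mmd2 (-0.219 ± 0.0685 SE per year, males minus females), Pnn (-0.198 ± 0.0646), Dtx3l (0.217 ± 0.0709), Hsdl2 (0.236 ± 0.0774) and Arl14 (-0.24 ± 0.0806). With limma 0 of 7151 genes passed, the lowest adjusted p was 1, and 98 had an unadjusted p below 0.05. With all 36 mice as deposited these counts were 0 and 25.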

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

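Of the tests given in this part, the exchange of the tables, the order of handling, the single membranes, the age of the 2 mice and the use of 1 mouse left out as a test of an explanation were chosen after the result was seen.

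The columns of 2 mice, mouse 66 (male replicate 5 of 704 to 743 days) and mouse 67 (a female of that age), stood apart from the rest. The male's correlation with its own table was 0.128 on array A (nearest mouse of its group 0.972) and -0.012 on array B (nearest 0.97). An exchange of columns between the tables predicts a higher correlation with the other table, and the lowest such value was 0.694. As the whole cause an exchange is argued against by the highest value after exchange, 0.79, which lies below the lowest of the 34 mice on each array (0.839 and 0.962). A curved change of scale may add to it: the rank correlation after exchange reached 0.883 on array A, above the lowest of the 34 mice (0.828), but 0.828 on array B, below theirs (0.968), so the tables leave this open, while age is argued against by the 5 other mice of 704 to 743 days, at 0.97 or above on both arrays.

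Mice with neighbouring running numbers in the titles resembled each other after age and sex were taken out. The 43 pairs numbered 1 to 3 apart had a mean correlation of 0.112, against -0.0233 when numbers were permuted within age range and sex (1-sided permutation p = 2e-04). This shows the likeness itself and does not tell the order of handling from other causes tied to the number. As the cause of this likeness, faults of single membranes are argued against, since the similarity of pairs of mice on array A and on array B correlated at r = 0.847. This does not mean that such faults were small. Deviations of clones 22 rows apart correlated at a mean r of 0.439 on array A and 0.402 on array B. The middle position correction took the median residual SD of a gene from 0.158 to 0.124. Most neighbours share an age range, 15 of the 16 pairs numbered 1 apart, and no biological explanation was tested.

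The erythroid and ribosomal lists were lower in the oldest mice, with list means of -0.085 and -0.046. As a test of brightness, both means lay at percentile 0 of 10000 random lists of like level. Such lists ignore the correlation between genes of a list, estimated at 0.149 (erythroid) and 0.489 (ribosomal). Their spread is therefore too narrow, and the percentile does not decide on brightness. The random lists show only that genes of like level were shifted less, with medians of -0.0168 and 0.00222. The spread between mice may account for both, with exact 2-sided permutation p-values of 0.0529 (erythroid) and 0.43 (ribosomal) over 756 splits. These tests used fits to the mice of the 2 age ranges alone, with differences of -0.0813 and -0.0502. A single mouse is argued against for the erythroid list, which stayed at -0.0682 or lower with any mouse left out, but not for the ribosomal list, which was at -0.0059 without male replicate 1 of 704 to 743 days. Age itself stays open and was tested on the same data.

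The difference between the sexes in the age slope of the ribosomal list had an adjusted p of 0.00617 (camera, preset correlation, all mice fitted) and of 0.871 with an estimated correlation.

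Single mice lay far from the others of their group by Dixon's ratio in 55 of 693 sets of values (7.94%), where chance gives about 1 in 20. Male replicate 1 of 17 to 44 days held 15 of them and female replicate 1 of that age 7. Male replicate 1 correlated with its own table at 0.839 on array A (nearest of its group 0.988) and 0.962 on array B (nearest 0.99). The other sets are given with the nearest value of the group in brackets. Female replicate 2 of 476 to 499 days had values of 0.52 for Alkbh1 (0.35), -0.65 for Exd2 (-0.98), 0.165 for Fen1 (-0.155) and 0.539 for the ribosomal protein list mean (0.194). Male replicate 3 of 704 to 743 days had values of 0.18 for Alox5ap (-0.09), 0.11 for Fen1 (-0.2) and 0.97 for Pcnx (0.52). Male replicate 5 of 476 to 499 days had values of -1.1 for Anxa1 (-0.65) and 0.274 for the erythroid and heme list mean (0.443). Male replicate 1 of 17 to 44 days had values of -0.79 for C1galt1 (-1.75), -1.73 for Chek1 (-1.02), -1.72 for Ctsl (-0.99), -1.45 for Eif2s3y (-0.65), -0.79 for H2-Eb1 (-0.12), 0.735 for Kdm6a (-0.22), 0.24 for Lgmn (-0.46), 0.19 for Lyz2 (1.05), -0.415 for Myo10 (-0.98), -1.55 for Pbdc1 (-0.8), -0.15 for Plrg1 (0.31), -0.72 for Rps28 (-0.28) and 0.0106 for the ribosomal protein list mean (0.193). Male replicate 3 of 169 to 194 days had values of 0.14 for Cd74 (-0.06) and 1.01 for Zfp981 (0.92). Male replicate 4 of 704 to 743 days had values of 1.48 for Ceacam1 (1.38), -0.09 for Col2a1 (-0.2) and -1.43 for Uty (-1.33). Female replicate 1 of 17 to 44 days had values of -0.1 for Chchd2 (-0.35), 0.25 for Cybb (0.55), -1.5 for E2f5 (-1.08), -1.72 for Hsdl2 (-1.49), -1.04 for Pnn (-0.83), -0.42 for Rpl5 (-0.0325) and 0.27 for Rpl7l1 (0.415). Female replicate 3 of 169 to 194 days had values of -0.09 for Chchd2 (-0.41) and -1.57 for Myo10 (-1.1). Female replicate 3 of 476 to 499 days had a value of -0.54 for D5Ertd579e (-0.39). Male replicate 4 of 476 to 499 days had values of -0.793 for Ddx3x (-0.963) and -1.17 for U2surp (-1.07). Male replicate 1 of 704 to 743 days had values of -0.78 for Eif2s3y (-0.55), -0.57 for Ppp1r2 (-0.71) and -0.21 for Rps28 (-0.05). Male replicate 2 of 17 to 44 days had a value of -0.39 for Fcer1g (-0.92). Male replicate 5 of 169 to 194 days had a value of -1.73 for Hsdl2 (-1.54). Male replicate 2 of 476 to 499 days had a value of -1.73 for Hsdl2 (-1.65). Male replicate 1 of 476 to 499 days had a value of -1.1 for Irf8 (-0.71). Female replicate 1 of 169 to 194 days had a value of -0.22 for Naaa (-0.66). Male replicate 2 of 169 to 194 days had a value of 0.67 for Rpa2 (0.89). Female replicate 2 of 17 to 44 days had values of -0.06 for Rps28 (-0.25) and -1.28 for Thnsl1 (-0.92). Male replicate 4 of 169 to 194 days had a value of -1.13 for Tbc1d8 (-0.76).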

How the results depend on the processing

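The alternatives with all 36 mice, the exchange, mice 1 and 2, position, surrogate variables, array weights and the running number for lists, the pairs of neighbours and all list results for 476 to 499 days and the slope by sex were chosen after the data were seen. Of 313 counts of genes over all settings, or of clones where these were fitted singly, all but 1 were 0. The exception was 1 gene, Aen, named here after its value was seen, from 17 to 44 to 169 to 194 days with surrogate variables (0.236 ± 0.0383 SE, adjusted p = 0.00794 with limma, 0.999 in the reported fit). The cause was not tested. All other settings called 0 genes (limma). Over the alternatives in this comparison, surrogate variables included and single mice left out not included, 66 to 554 genes, or clones where these were fitted singly, had an unadjusted p below 0.05. The number tested was not the same in all: there were more clones than genes, and the filter on dim genes left fewer genes. With every mouse left out in turn 0 genes passed (lowest 0, highest 0) in all 6 comparisons.

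The number of lists called from 17 to 44 to 169 to 194 days went from 1 to 0 with array weights, all 36 mice, the exchange, mice 1 and 2 left out, an estimated correlation or fry, and to 2 with the smaller and the larger position correction; with 1 mouse left out it was 0 to 2. For 704 to 743 days it went from 2 to 0 with an estimated correlation or fry, and to 1 with the middle position correction. It was also 0 with all 36 mice as deposited, where 2 of the oldest mice follow the other table, so this does not test the calls. With 1 mouse left out it was 1 to 2. For sex it went from 0 to 1 with array weights, all 36 mice, the exchange or the smaller position correction, and to 2 without mice 1 and 2 or with the other position corrections; with 1 mouse left out it was 0 to 2. For the age slope it went from 0 to 2 with array weights or the smaller position correction and to 1 with the middle one; with 1 mouse left out it was 0. For the slope by sex it went from 1 to 0 with array weights, without mice 1 and 2, with an estimated correlation or fry; with 1 mouse left out it was 0 to 1. The cause was not tested. Over the settings other than single mice left out, the adjusted p was 0.0048 to 0.253 for the monocyte list (169 to 194 days), 9.68e-05 to 0.96 for the erythroid and 7.95e-05 to 0.98 for the ribosomal list (704 to 743 days), and 0.000159 to 0.871 for the ribosomal list (slope by sex). With 1 mouse left out these were 0.00366 to 0.198, 0.000225 to 0.00988, 0.000527 to 0.962 and 1.14e-09 to 0.602.

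Of 5158 values of named genes over all settings 5099 kept their direction and side of the threshold. Those that turned sign, none of which passed in any setting, were: with array weights, Cecr2 (age slope) 0.0157 and Eif2s3y (sex) 0.0285; with all 36 mice as deposited, Csf3r (age slope) -0.212, Cybb (age slope) -0.0262, D5Ertd579e (age slope) 0.0076, Mbnl3 (704 to 743 days) -0.226, Mgst1 (704 to 743 days) 0.0632, Nisch (704 to 743 days) 0.105, Prdx3 (704 to 743 days) 0.15, S100a9 (age slope) -0.357, Tcf3 (age slope) 0.0337, Tubb2a-ps2 (704 to 743 days) -0.177, Uty (sex) -0.0729, Vps26c (704 to 743 days) -0.00668 and Zfp36l2 (704 to 743 days) 0.219; with the 2 mice exchanged back, Ctsl (age slope) -0.0911, Eri3 (704 to 743 days) 0.174, Rps3a1 (704 to 743 days) 0.149 and Tcf3 (age slope) 0.00468; with the position correction over the middle neighbourhood, Cybb (age slope) -0.00639, Eif2s3y (sex) 0.00161, Hapln1 (169 to 194 days) 0.0527, Kdm6a (sex) -0.00101 and Lpl (sex) -0.0261; with that over the smaller one, Cybb (age slope) -0.0136, Hapln1 (169 to 194 days) 0.0717 and Lpl (sex) -0.0399; with that over the larger one, Cybb (age slope) -0.00171, Eif2s3y (sex) 0.0122, Hapln1 (169 to 194 days) 0.0556 and Lpl (sex) -0.0169; with mice 1 and 2 left out, Eif2s3y (sex) 0.0439, Lpl (sex) -0.000152 and Rpl5 (169 to 194 days) -0.0134; with surrogate variables, Eif2s3y (sex) 0.0131 and Tcf3 (age slope) 0.00403; with mice of 169 days and older alone, Tcf3 (age slope) 0.00329. The cause was not tested. With 1 mouse left out, Col9a3 (169 to 194 days) was at -0.0499 to 0.02, Hapln1 at -0.0405 to 0.0227, Eif2s3y (sex) at -0.0644 to 0.0376 and Uty at -0.0305 to 0.0329. Quantile normalization, rounds and covariate of the running number and leaving out mouse 27 changed no direction, no call over all genes and no list call; the first 2 held for single tables, log of age and trend and robust eBayes, with which lists were not tested. Ighm lost its pass when adjusted over the list alone with quantile normalization (adjusted p = 0.0619), rounds (0.0594), without mouse 27 (0.0982) and with log of age (0.287). Signal over background is not given in the sources used here, so what it limits was not analysed here. As a paired analysis, 15 pairs of a male and a female of 1 age range with neighbouring running numbers were fitted with a replicate block. The deviations of 8 pairs correlated above 0.1 (lowest -0.211, highest 0.351). Their mean was 0.109, against -0.0266 over all pairs of mice, so these neighbours were alike on average. The reported fits and the splits for sex do not take such pairs into account. With the block 0 genes passed for sex (limma; 106 at an unadjusted p below 0.05) and 0 for the slope by sex (101), 0 and 1 lists were called, and Xist was at -0.257 ± 0.0641 SE (adjusted p = 1).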

Other observations

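The 12 neutrophil genes had a list mean (± SD over mice) of 0.684 ± 0.0669 (n = 9) at 17 to 44 days, 0.733 ± 0.116 (n = 10) at 169 to 194 days, 0.744 ± 0.109 (n = 10) at 476 to 499 days and 0.789 ± 0.0599 (n = 5) at 704 to 743 days. The 7 B-lineage genes had means of -0.29 ± 0.0579 (n = 9) at 17 to 44 days, -0.286 ± 0.0615 (n = 10) at 169 to 194 days, -0.252 ± 0.0708 (n = 10) at 476 to 499 days and -0.276 ± 0.0454 (n = 5) at 704 to 743 days. The 21 haemoglobin clones all had negative slopes with age, from -0.138 to -0.0258 per year, and from 17 to 44 to 169 to 194 days 18 were lower and 3 higher. These values were chosen after they were seen and no test of them was added.

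Each count was set against splits of the mice, with age exchanged within sex or sex within age range, 100 splits per comparison with the real one included; the prediction for each test was written before its result was seen.

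For genes passing, the real count was 0 in each comparison, which any split reaches (100 of 100), so these splits decide nothing about chance; the highest other split called 568 genes for the age slope, 143 genes for the step to 169 to 194 days, 965 genes for 476 to 499 days, 74 genes for 704 to 743 days, 1 gene for sex and 424 genes for the slope by sex. Splits that call many genes would point to a structure among the mice, but only 1, 1, 4, 4, 1 and 2 of the other splits called any gene, in the same order. In simulated data without any change, 0 of 100 data sets called a gene for the age slope and 1 for sex. For the step to 169 to 194 days it was 5, and for 704 to 743 days 8. These data permute the residuals of the same mice and so keep any structure among them. Setting the splits against them therefore cannot tell whether such a structure is there. A likeness of mice with neighbouring running numbers was found by the test given above. The other 2 comparisons were not simulated in this way. For genes at an unadjusted p below 0.05, as many were found in 47 splits for the age slope (real 277, highest other 2100), 57 splits for the step to 169 to 194 days (real 264, highest other 1869), 55 splits for 476 to 499 days (real 234, highest other 2175), 70 splits for 704 to 743 days (real 136, highest other 1259), 96 splits for sex (real 88, highest other 1678) and 92 splits for the slope by sex (real 98, highest other 1880). For lists called by camera at the preset correlation, as many were found in 59 splits for the step to 169 to 194 days (real 1, highest other 4), 13 splits for 704 to 743 days (real 2, highest other 3) and 51 splits for the slope by sex (real 1, highest other 5). Chance was not excluded for these list counts nor for the unadjusted counts of genes. For lists with a real count of 0 the splits decide nothing either, and the highest other split called 4 for the age slope, 4 for 476 to 499 days and 5 for sex.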
